A study of Arabidopsis thaliana with 6 samples.

How the data were processed

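RNA from about 250 mg of seedlings per sample was labelled from 500 ng with a 3' in vitro transcription kit and hybridised to ATH1 arrays, per the labels. Plants grew on agar at 22 °C with 8 h of light and 16 h of dark for 20 days. The deposited values are on the log2 scale with 2 decimals, 1 column per array, and the submitters' processing notes name RMA and the affy package. Versions, and the genome build behind the probe sets, are not given in the sources used here. Scan dates and hybridization batches are not given there either, so a batch that followed genotype was not checked and would enter every mutant minus WT difference. RMA makes arrays alike in distribution, so a shift shared by most transcripts would not appear in these values. For arrays, the number of arrays limits the precision.

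Arrays were grouped by the genotype in their titles, 3 WT and 3 yaf9a yaf9b. The 64 control probe sets were left out of 22810, which left 22746. Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, mutant minus WT, no filter and no block), with Benjamini-Hochberg adjustment over all 22746 and a threshold of 0.05. The same scripts were tested on simulated data for this comparison with 22746 probe sets. They called 32.4% of 68 probe sets changed by 0.5 on the log2 scale, 78.1% of 64 changed by 1 and 100% of 68 changed by 2, and 9 of 149 calls were false. The simulation held far fewer changes than the data, with 149 calls against 2985, and its probe sets varied independently. Its shares therefore need not hold for the real comparison.

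Probe sets were named from GEO's platform annotation, with symbols and loci from the RefSeq table of assembly TAIR10.1. Of the 22746 probe sets, 13513 listed 1 gene, 503 listed several and were left unnamed, and 8730 listed none and are unnamed here. By gene ID, 13436 of those with 1 gene matched the RefSeq table. Gene lists used 1 probe set per gene, the one with the highest mean signal.

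The 26 gene lists fixed before the data were examined held 391 entries, of which 50 had a named probe set. No list had the 5 measured members a list test needed, so no planned list was tested as a set, and their members are given one by one. The lists on floral organ identity, phosphate starvation, nitrate response, DNA damage response and seed storage had 0 measured members and were not analysed here. After the annotation was seen, and before any list was tested, 27 lists were added: cytosolic ribosomal proteins, plastid-encoded and mitochondrion-encoded genes, and families sharing a name. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether a list's genes move on balance one way, each adjusted over the 27 lists. The sensitivity of 1 uncalled list is not reported here. On simulated data, 5.74% of list tests without a change had a camera p under 0.05, and a ribosomal list shifted by -0.3 was called in 20 of 20 simulations. The simulated probe sets varied independently, whereas the lists that camera called in the data had estimated correlations from 0.249 to 0.625. These rates therefore do not show how often camera falsely calls lists so correlated.

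The text names YAF9A, YAF9B and FLC, and the 10 genes with the largest rise and the 10 with the largest fall among probe sets past the threshold that listed 1 gene and had separate genotypes. It also names up to 4 passing members of each list by smallest p, or 2 members where none passed. PDF1.2 was named after its values were seen. For the added lists this was limited to those called by camera or fry, a limit set after their values were seen. The 4 probe sets without a listed gene that had the largest changes are given without an identifier and were chosen after their values were seen.

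Alternatives were cyclic loess, centring on array medians, a trended and robust variance model, array quality weights, a filter at the 40th percentile of mean signal, leaving out probe sets with the suffix _s_at or _x_at, the mean over the probe sets of a gene, the replicate number as a block, leaving out each array, and a 1.5-fold minimum change. Calls ended by the block are given together where the dependence on the processing is described.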

Results

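Transcript levels were measured on Affymetrix ATH1 arrays in whole seedlings of Arabidopsis thaliana, ecotype Col-0. Wild type (WT) was compared with a yaf9a yaf9b double mutant. YAF9A and YAF9B encode subunits of the NuA4 complex, which acetylates histones, and of the SWR1 complex, which deposits the histone variant H2A.Z. Each genotype had 3 arrays from independent biological replicates, 6 in all, and that number limits the precision of every value. Seedlings were 20 days old, grown in short days and collected at ZT8, when the light period ended. The median signal per array lay between 5.99 and 6.06 on the log2 scale. Pearson correlations across probe sets were 0.993 to 0.995 between WT arrays, 0.989 to 0.996 between mutant arrays and 0.98 to 0.987 between genotypes. The first principal component held 57.4% of the variance and separated the genotypes.

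The comparison asked which transcripts differed between yaf9a yaf9b and WT seedlings. The largest falls with a gene name included THI2.1, a thionin induced by jasmonate, and 2 genes of jasmonate-catabolising dioxygenases, JRG21 (AT3G55970) and AT2G38240. The largest rises included the expansin-like gene EXLA1 and EXO, a brassinosteroid-responsive gene linked to cell expansion. Of 107 genes for cytosolic ribosomal proteins, 53 rose and 0 fell (median of all 1.29-fold higher), and of 69 genes encoded in the plastid genome, 20 fell and 0 rose (median of all 1.36-fold lower). In all, 2985 of 22746 probe sets changed at a limma adjusted p under 0.05, 1482 higher and 1503 lower in the mutant.

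The 2985 changed probe sets were 13.1% of those tested, and 6317 passed an unadjusted p of 0.05. Of the changed probe sets, 250 were higher and 135 lower by at least 2-fold, and the median absolute change was 0.56 on the log2 scale (1.47-fold). By at least 4-fold, 32 were higher and 38 lower. All 2985 had every mutant array on the same side of every WT array, as had 7177 of all probe sets (31.6%, against 10% by chance). The count was 963 without mutant array 2, 1380 without WT array 2 and 1924 without mutant array 1, each fit having 1 array fewer. The targeted genes YAF9A and YAF9B, and the floral repressor FLC, had 0 probe sets listed under their loci in the annotation used, so they were not analysed here and the genotype labels were not checked by the targeted transcripts.

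Among the 10 named genes with the largest rises, AT3G15440 rose most, from 5.45 ± 0.562 to 8.62 ± 0.217 (log2 signal, mean ± SD, n = 3 arrays per genotype here and below), a 9.02-fold change (limma adjusted p = 0.00079). AT1G77640, which encodes an ERF family transcription factor, rose by 2.91 ± 0.698 (log2 change ± SE; adjusted p = 0.0315). EXLA1 rose 5.35-fold (log2 change 2.42 ± 0.287, adjusted p = 0.003) and EXO 4.97-fold (2.31 ± 0.247, adjusted p = 0.00218). AT3G19680 rose by 2.28 ± 0.111, AT2G27080 by 2.27 ± 0.428, AT5G57650 by 2.25 ± 0.139 and AT1G65370 by 2.16 ± 0.117. AT5G59670 and AT5G55450 rose by 2.15 ± 0.37 and 2.14 ± 0.391. The call for AT1G77640 ended without WT arrays 1, 2 or 3 and without mutant arrays 1 or 2 (adjusted p 0.0669, 0.105, 0.0838, 0.0851 and 0.0896) and with a trended, robust variance model (0.137), which also ended those of AT2G27080 (0.0687) and AT5G55450 (0.0594). Without WT array 2 the adjusted p was 0.0571 for AT2G27080, and without mutant array 2 it was 0.0544 for AT5G55450 and 0.0523 for AT5G59670. The 7.53-fold change of AT1G77640 was 4.64-fold without mutant array 2 and 14.4-fold without mutant array 3.

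Among the 10 named genes with the largest falls, THI2.1 went from 7.42 ± 0.691 in WT to 3.68 ± 0.206 in the mutant, 13.4-fold lower (limma adjusted p = 0.00079). JRG21 was 13.3-fold lower (log2 change -3.73 ± 0.51, adjusted p = 0.00453) and AT2G38240 5.82-fold lower (-2.54 ± 0.316, adjusted p = 0.00356). AT3G28220 was 9.25-fold lower (-3.21 ± 0.214), and the orphan gene QQS, which affects starch and protein content, was 6.35-fold lower (-2.67 ± 0.25). CYP71B22, a cytochrome P450, fell by 2.71 on the log2 scale (SE 0.592, adjusted p = 0.023). GH3.3, which encodes an enzyme that conjugates auxin to amino acids, was 5.67-fold lower with an adjusted p of 0.0498 and a WT SD of 1.63. AT4G31310 (-2.5 ± 0.171), AT2G40960 (-2.37 ± 0.203) and AT4G11410 (-2.26 ± 0.097) fell as well. In WT arrays 1, 2 and 3, THI2.1 lay at 6.65, 7.64 and 7.98, and JRG21 at 7.87, 9.24 and 9.87. AT2G38240, CYP71B22 and GH3.3 rose in the same order of WT arrays, so the falls of these genes need not be separate observations. AT3G28220, QQS, AT4G31310, AT2G40960 and AT4G11410 did not follow that order. The GH3.3 call ended without WT arrays 2 or 3 (adjusted p 0.151 and 0.0848), without mutant arrays 1, 2 or 3 (0.0798, 0.15 and 0.0942), after cyclic loess (0.0578) and with a trended, robust variance model (0.179). The CYP71B22 call ended without WT array 2 (0.088), without mutant array 2 (0.0897) and with that variance model (0.107). With the replicate number as a block, the calls of GH3.3 and CYP71B22 ended as well (0.107 and 0.0613). The size of the GH3.3 change was 10.3-fold without WT array 1 and 3.36-fold without WT array 3, and that of CYP71B22, 6.53-fold over all arrays, was 11.2-fold and 4.24-fold.

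**Figure D1:**
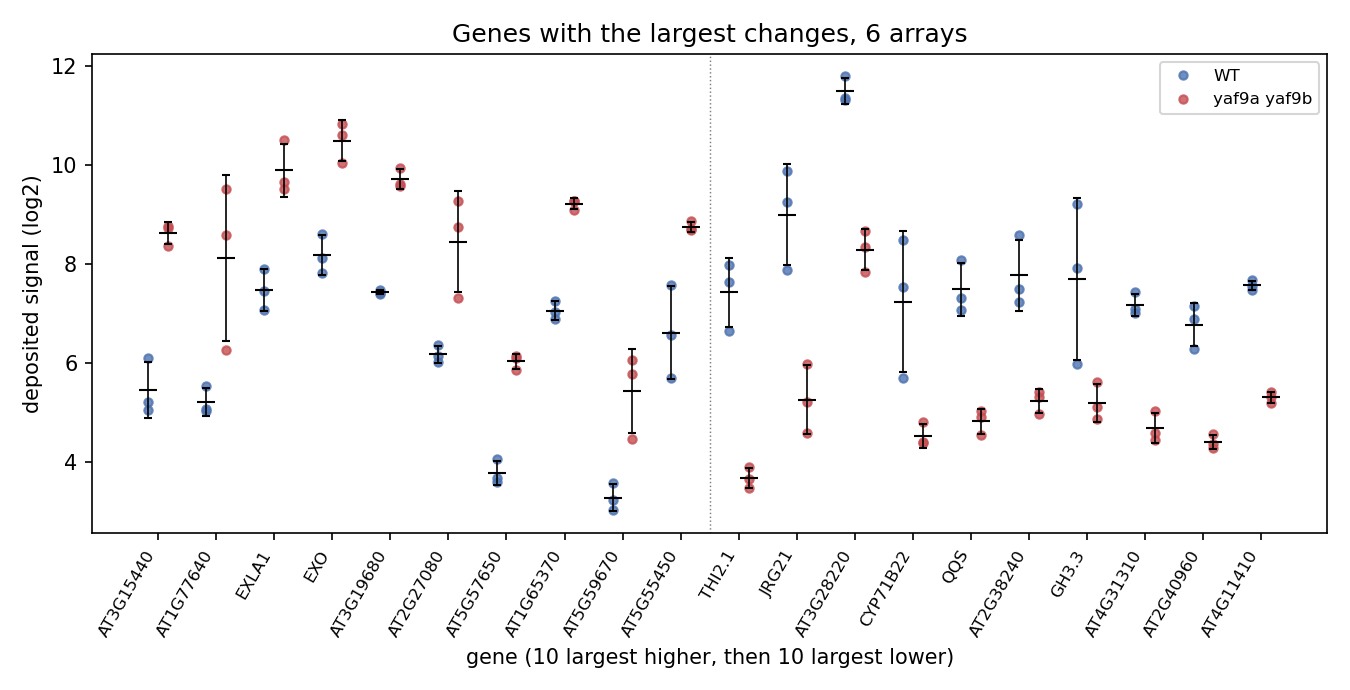
Deposited log2 signal (vertical axis) of the 10 named genes with the largest rises and the 10 with the largest falls (horizontal axis) in the 3 WT and 3 yaf9a yaf9b arrays; points are arrays, and bars give the mean and SD. THI2.1 lay at 7.42 in WT and 3.68 in the mutant on average. No gene had overlapping genotypes, which was a condition for choosing these genes.

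Among probe sets without a listed gene, the 2 with the largest falls fell by 4.28 and 3.81 on the log2 scale, with SEs of 0.83 and 0.514 (limma adjusted p = 0.0157 and 0.00446). The 2 with the largest rises rose by 3.59 ± 0.475 and 3.08 ± 0.202 (adjusted p = 0.00415 and 0.000435). The call of the larger fall ended without WT array 2 (0.0583), without mutant array 2 (0.0661) and with the trended, robust variance model (0.0906). Without mutant arrays 1 and 3 in turn, the log2 changes of the larger fall were -5.18 and -3.42, and those of the other were -4.45 and -3.22.

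Of the chromatin and flowering genes fixed before the data were examined, SWC2, a subunit of SWR1, fell by 0.48 on the log2 scale (SE 0.092, limma adjusted p = 0.0149), and the other 2 measured genes among SWR1, NuA4 and H2A.Z subunits did not pass. AGL24, a MADS-box promoter of flowering, rose 1.6-fold (log2 change 0.68 ± 0.099, adjusted p = 0.00561), 1 of 4 measured floral promoters. AT1G69570, the floral repressor CDF5, rose 1.86-fold (0.9 ± 0.098, adjusted p = 0.00225), 1 of 3 measured floral repressors. The FLC regulators LD and FY did not pass, with log2 changes of -0.25 ± 0.1 and 0.19 ± 0.117. The morning clock gene AT5G52660 (RVE6) fell 1.97-fold (-0.98 ± 0.133, adjusted p = 0.0045), and the evening gene GI did not pass (-0.16 ± 0.088). The SWC2 call ended without WT array 2 (adjusted p = 0.054) and without mutant array 2 (0.0542).

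Of the 17 genes of the auxin and shade growth list, only 4 had a named probe set, and these 4 changed. IAA29, an auxin-inducible repressor of auxin signalling, rose 3.68-fold (log2 change 1.88 ± 0.177, limma adjusted p = 0.00135). HAT2, an auxin-inducible homeodomain gene, rose by 0.7 ± 0.127 (adjusted p = 0.0124), and WES1 (GH3.5), which encodes a conjugating enzyme like that of GH3.3, by 0.55 ± 0.143 (adjusted p = 0.0414), whereas GH3.3 fell. The HAT2 call ended without mutant array 2 (adjusted p = 0.0581), and the WES1 call ended without any array except WT 3 (0.104 without WT 1, 0.104 without WT 2, 0.0957 without mutant 1, 0.103 without mutant 2 and 0.0865 without mutant 3). The gibberellin receptor genes GID1A and GID1B did not pass (0.09 ± 0.09 and -0.04 ± 0.176).

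The cold-regulated genes COR15A and COR15B, whose products protect chloroplast membranes in the cold, fell by 0.71 and 0.96 on the log2 scale (SE 0.107 and 0.156, limma adjusted p = 0.00644 and 0.0086). They were 2 of the 4 measured genes of the cold, drought and abscisic acid list, and all 4 fell when adjusted over the list alone. DFR, an enzyme of anthocyanin synthesis, fell by 0.66 (SE 0.119, adjusted p = 0.012), the 1 changed gene of 3 in its list. SAG101, a partner of EDS1 in immunity, rose by 0.77 ± 0.153 (adjusted p = 0.0166), and AKINBETA1, a subunit of the SnRK1 kinase that responds to low energy, rose by 0.7 ± 0.116 (adjusted p = 0.00918). Each was the only measured gene of its list, salicylic acid defence and carbon starvation. In the jasmonate list THI2.1 fell, 1 of 2 measured. The other, PDF1.2, did not pass (log2 change -1.68 ± 1.32, limma adjusted p = 0.47), and its WT arrays varied widely, at 5.31, 10.21 and 10.92. Without mutant array 2 the calls of DFR and SAG101 ended (adjusted p = 0.0599 and 0.0696). With the replicate number as a block, those of DFR and AKINBETA1 ended (0.0534 and 0.0517).

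The lists on glucosinolate synthesis, iron deficiency, heat shock, the cell cycle and the thalianol and marneral clusters held no member past the threshold. BCAT4, which acts in glucosinolate synthesis, had a log2 change of -0.45 ± 0.133 (limma adjusted p = 0.0629). It was the only measured gene of its list, so adjustment over the list alone left its unadjusted limma p of 0.00945. The iron deficiency regulators PYE and BHLH101 had log2 changes of -0.39 ± 0.148 and -0.23 ± 0.202. The heat shock genes AT5G48570 and ATHSP22.0 had -0.23 ± 0.128 and 0.11 ± 0.089, the mitotic kinase gene AUR1 had 0.24 ± 0.128, and AT5G47980 of the thalianol cluster had 0.11 ± 0.201. BCAT4 passed without WT array 1 (adjusted p = 0.0455) and with the trended variance model (0.037), PYE and BHLH101 passed without WT array 1 (0.042 and 0.0461), and AT5G48570 passed without mutant array 3 (0.0433).

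Tissue markers were compared because the samples were whole seedlings. Of 4 measured nuclear genes of photosystems and Rubisco, LHCB4.2, an antenna protein of photosystem II, fell by 0.33 on the log2 scale (SE 0.088, limma adjusted p = 0.0434). The other 3 did not pass, and the median of the 4 was -0.06. The root markers PYK10 and EXPA18 did not pass (-0.15 ± 0.149 and 0.07 ± 0.188). The LHCB4.2 call ended without each array in turn (adjusted p 0.0521 to 0.158) and after centring on array medians (0.0631). In the fixed lists not named here with a count of their own, adjustment over the list alone called the same number as adjustment over all probe sets.

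Cytosolic ribosomal proteins make up the protein part of the ribosomes outside the organelles. Of their 107 measured genes, 53 rose and 0 fell at a limma adjusted p under 0.05, 105 lay above 0 and the median log2 change was 0.37. At an unadjusted p of 0.05, 89 were higher and 0 lower. AT5G67510 rose by 0.87 ± 0.103, AT3G06700 by 0.84 ± 0.082, AT3G53890 by 0.71 ± 0.088 and AT5G60670 by 0.7 ± 0.097 (adjusted p 0.00301, 0.00158, 0.00354 and 0.00469). The list passed camera at a preset correlation of 0.01 (adjusted p = 4.25e-27) and fry (0.0348), but not with an estimated correlation (adjusted p = 0.494 with an estimated correlation). Of the 3 measured genes of the shorter list fixed before the data were examined, AT5G02870 rose by 0.44 ± 0.112 (adjusted p = 0.04), and 3 rose when adjusted over the list alone. The AT5G02870 call ended after cyclic loess (adjusted p = 0.052) and without any array except WT 1 (0.0998 without WT 2, 0.0809 without WT 3, 0.0927 without mutant 1, 0.139 without mutant 2 and 0.0659 without mutant 3).

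The plastid genome encodes parts of the photosynthetic complexes and of the plastid's own gene expression machinery. Of 69 measured plastid-encoded genes, 20 fell and 0 rose at a limma adjusted p under 0.05, and 68 lay below 0, with a median log2 change of -0.44. At an unadjusted p of 0.05, 43 were lower and 0 higher. Of 33 genes for photosystem, cytochrome b6f, ATP synthase and Rubisco subunits, 7 fell (median -0.4), among them psaI of photosystem I by 1.11, the ATP synthase genes atpF by 0.94 and atpH by 0.87, and psbD, the D2 protein of photosystem II, by 0.78 on the log2 scale. Of 10 genes of the NDH complex, which carries electrons around photosystem I, ndhG, ndhJ and ndhK fell by 1.04, 0.96 and 0.95 (median -0.58). Of 19 genes for plastid ribosomal proteins and RNA polymerase, 6 fell (median -0.3), including rps2 by 0.65, rps4 by 0.5, rpl16 by 0.46 and rpl36 by 0.39. The 3 lists passed camera at the preset correlation (adjusted p = 6.46e-10, 2.82e-06 and 2.89e-05), none with an estimated correlation (adjusted p = 0.494 with an estimated correlation for each), and none by fry (0.052, 0.052 and 0.0943). The median of the ribosomal and polymerase list was -0.18 without WT array 2, and calls of atpF, ndhG, rps4, rpl16 and rpl36 ended without mutant array 2 (adjusted p 0.0505, 0.134, 0.0504, 0.103 and 0.0829). Calls also ended for ndhG without WT 1, WT 2 or mutant 3 (0.0642, 0.0566 and 0.0604), for rpl16 without WT 1, WT 3 or mutant 1 (0.0973, 0.0824 and 0.0912) and after median centring (0.0534), and for rpl36 without WT 2, WT 3 or mutant 1 (0.0703, 0.0585 and 0.0741).

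**Figure D2:**
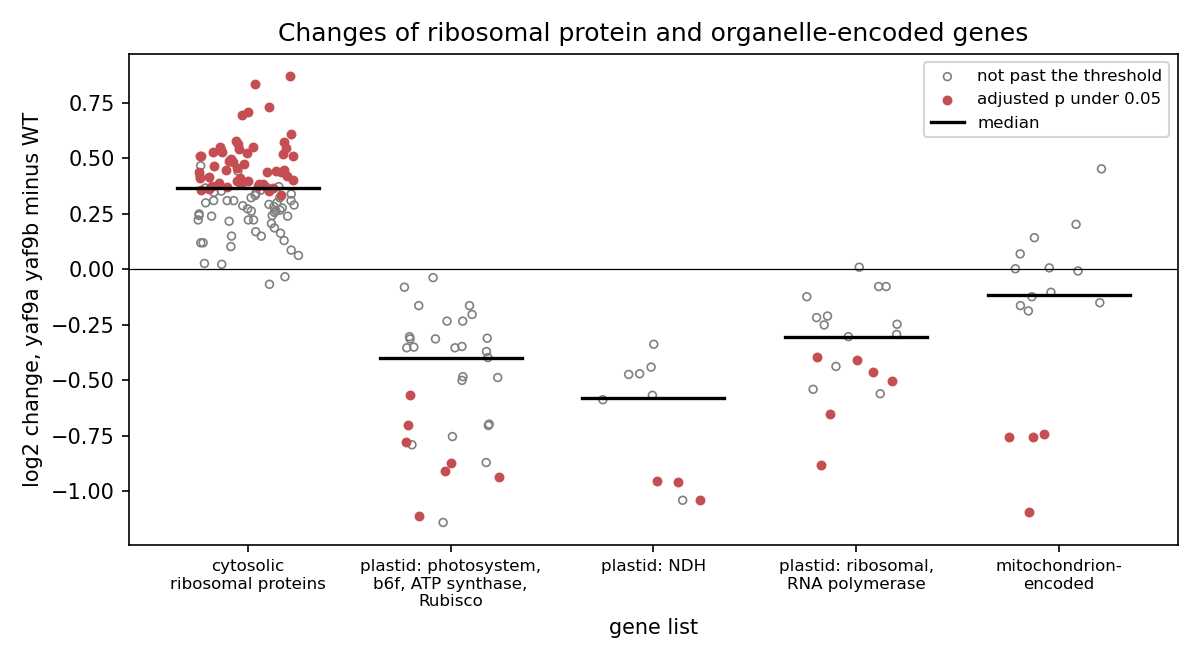
Log2 change, yaf9a yaf9b minus WT (vertical axis), of each measured gene in 5 gene lists (horizontal axis); filled points passed an adjusted p of 0.05, open points did not, and lines are medians. The ribosomal protein genes centred on 0.37 and the plastid photosystem list on -0.4.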

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

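The list tests rest on lists added after the annotation was seen; the other alternatives were planned. The count of 2985 changed probe sets (1482 higher, 1503 lower) stayed within 1.5 times under cyclic loess, median centring (56.7% higher, against 49.6%), the trended variance model, the dim filter and the suffix filter. Array quality weights gave 4278, of which 2298 were lower; the cause was not tested. The mean per gene gave 1589 (765 higher, 824 lower) because fewer features were tested, and a 1.5-fold minimum gave 1366 (779 and 587) by construction. Leaving out 1 array gave 963 to 2684 changed (557 to 1401 higher, 406 to 1283 lower) with fewer arrays. The lowest counts came without mutant array 2 (963, of which 954 were among the reported ones), WT array 2 (1380) and mutant array 1 (1924), and the lower count was also 955 without WT array 1. With the replicate number as a block, 1233 changed (693 higher, 540 lower), 1208 of them among the reported ones. Deviations from the genotype means correlated at -0.21, 0.01 and -0.32 between arrays of the same number, and no array correlated best with the array of its own number. These values gave no sign that the number pairs the arrays, but with 3 arrays per genotype they cannot exclude pairing. No changed probe set reversed in any of these fits on probe sets. Only cyclic loess and median centring could have reversed one. All 2985 had separate genotypes, and the other fits kept the deposited values. Of 57 named genes past the threshold, 32 kept the call in every alternative run and 25 lost it in at least 1, in 97 of 792 comparisons of these genes, of which 69 left out an array and 17 used the block. The block ended the calls of AT1G77640, CYP71B22, GH3.3, SWC2, LHCB4.2, DFR, AKINBETA1, WES1, AT5G02870, ndhG, rpl36, rpl16, ccb382, ccb452, BZIP53, bZIP52 and BZIP28 (limma adjusted p 0.0517 to 0.121). It also ended that of the larger fall among probe sets without a listed gene (0.0669), and BCAT4 passed with it (0.0499).

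The number of lists called by camera was 4 in most settings, 5 without dim probe sets and 4 to 6 leaving out 1 array. It was 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. Fry, which asks another question than camera, called 3. The lists called by fry were the ribosomal protein, mitochondrion-encoded and bZIP lists, so the 3 plastid lists were lost (adjusted p 0.052, 0.052 and 0.0943). The ribosomal protein median ran from 0.32 to 0.41, and the plastid medians from -0.55 to -0.29, -0.76 to -0.42 and -0.37 to -0.18, over the alternatives. No called list reversed. Only genes and families not called as reported changed direction, and the cause was not tested. Called genes could hardly reverse, since their genotypes were separate. Leaving out 1 array, AT5G47980 ran from -0.03 to 0.36, EXPA18 from -0.09 to 0.24, GID1B from -0.15 to 0.15 (0.09 with array weights) and PYK10 from -0.25 to 0.02. The direction of the list test also turned, at these medians: BGLU at -0.02 by fry and 0.02 without dim probe sets; GSTU at 0 with array weights, 0.24 without dim probe sets and -0.1 to 0.06 leaving out 1 array; SWEET at 0.06 by fry and 0.01 to 0.09; VPS at -0.03 with array weights, -0.08 after cyclic loess, -0.1 without dim probe sets and -0.12 to -0.04; core histones at -0.01 without dim probe sets and -0.14 to -0.03. Leaving out 1 array, it turned for CYP (-0.03 to 0.09), EXPA (-0.09 to 0.1), TRM (0.04 to 0.11) and class III peroxidases (0.05 to 0.14). The alternatives for YAF9A, YAF9B, FLC and the planned lists as sets gave no value and were not run. No detection call was used here, so a dim probe set's change is limited by signal near background.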

Other observations

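The tests of RNA quality, organelle RNA capture, control probe sets and plastid genes of like signal, the wider jasmonate list, and the demand that a bound be passed by more than its spread were chosen only after results were seen, and the other gene lists after the annotation was. Of 16 measured genes encoded in the mitochondrial genome, 4 fell at a limma adjusted p under 0.05: ccb382 and ccb452, which act in cytochrome c maturation, by 1.09 and 0.74 on the log2 scale, and nad1 and nad9 of respiratory complex I by 0.75 and 0.76. The list's median was -0.11, fry called it (adjusted p = 0.0413) and camera did not (0.167; adjusted p = 0.494 with an estimated correlation). Over the alternatives this median ran from -0.15 to -0.07. Calls ended without mutant array 2 for ccb382 (0.0599) and nad9 (0.0575), without WT array 2 for ccb382 (0.0534) and ccb452 (0.072), and for ccb452 also without WT array 1 (0.0575) and mutant array 1 (0.0549).

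Among 14 bZIP transcription factor genes, bZIP44, BZIP53 and bZIP52 rose by 1.03 ± 0.109, 0.67 ± 0.13 and 0.54 ± 0.133, and BZIP28, a regulator of the unfolded protein response, fell by 0.37 (SE 0.09) on the log2 scale. Fry called the list (adjusted p = 0.0413) and camera did not (0.275; adjusted p = 0.494 with an estimated correlation). BZIP28 lost its call without each array in turn (adjusted p 0.0633 to 0.102), after cyclic loess (0.0588) and after median centring (0.0518), and bZIP52 without any array except WT 1 (0.0503 to 0.0894). BZIP53 lost its call without WT array 2 (0.0558) and mutant array 2 (0.0729). The other 21 added lists were called by neither test, with medians from -0.18 to 0.18 and lowest adjusted p of 0.0911 for camera and 0.052 for fry. The RALFL peptide genes were called by camera without mutant array 3 (median 0.24, adjusted p = 0.0409) and without dim probe sets (0.43, 0.0437), and class III peroxidase genes without mutant array 3 (0.1, 0.0409). Over all arrays and probe sets neither list passed camera at the same preset correlation (adjusted p = 0.0911 for RALFL and 0.708 for the peroxidases). Neither passed the other setting of camera (adjusted p = 0.494 with an estimated correlation for RALFL and adjusted p = 0.924 with an estimated correlation for the peroxidases).

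Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed probe sets as the genotypes, the genotype split itself, with 2985. The highest of the other splits was 0 by limma, with 170 to 1705 probe sets at an unadjusted p under 0.05. Each of the other splits mixed the genotypes, so the genotype difference added to the spread within its groups. This held their counts down, so the 0 cannot serve as a measure of chance. With 10 splits the share cannot fall under 0.05.

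Cytosolic ribosomal protein transcripts were higher in each of the 3 mutant arrays, at medians of 0.37, 0.35 and 0.39 above the WT mean, against 0.08, -0.08 and 0 in the WT arrays. A general shift of bright probe sets is argued against, since 95% of 10000 lists matched on mean signal had medians between -0.07 and 0.02, and 0.07 was the highest, against 0.37. A single array is argued against as well, since the median stayed at 0.33 or more without any 1 array. Higher expression of ribosomal protein genes in yaf9a yaf9b seedlings, directly or through a difference in growth, may account for it. This hypothesis came from the same data, neither route was tested, and the list lost its call with an estimated correlation. A difference in growth stage between the samples was not tested.

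Plastid-encoded transcripts were lower in the mutant arrays, at medians of -0.56, -0.36 and -0.36 against the WT mean, with 0.02, 0.18 and -0.17 in the WT arrays. RNA degradation stays open: the 3' minus 5' signal of 6 control pairs was 0.099 higher in the mutant (SE 0.111; 1.71 ± 0.19 in WT and 1.81 ± 0.04 in the mutant, SD, n = 3; two-sided exact permutation p = 0.4, with 0.1 the smallest this design allows). Lower capture of organelle RNA with short poly(A) tails cannot be told apart from a lower plastid transcript level. The median of the 60 plastid genes at or above the 40th percentile of mean signal was -0.42. That median minus the median of the 8 mitochondrial genes as bright was -0.33, with a 95% bootstrap interval from -0.66 to 0.38. The interval came from resampling genes and not arrays, so it does not measure the spread between replicates. Less green tissue stays open too, although the 4 nuclear photosynthesis genes had a median of -0.06 (SD 0.17), above the bound of -0.22 set beforehand. That bound ignored signal: at 12.3 or more, where these 4 genes lay, 8 plastid genes had a median of only -0.23, and -0.06 passed the bound by less than its SD.

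The falls of THI2.1, JRG21 and AT2G38240 prompted the hypothesis of a wider loss of jasmonate-induced transcripts, tested on a list without the genes already seen. Of its 45 genes 11 were measured, and 1 fell, AT1G54020, by 1.17 (limma adjusted p = 0.0102). Adjusted over the list alone, AT5G05600 (-0.78, limma adjusted p = 0.038) and JAL23 (-0.53, limma adjusted p = 0.0454) were lower too; the 3 were named after their values were seen, and 6 of 11 lay below 0. The list's median was -0.03 with a camera p of 0.226 (0.273 with an estimated correlation), so no shift of the list as a whole was detected among the 11 genes, and the other listed genes were not analysed here. AT3G11180, JMT and DGL had WT means of only 3.29, 3.35 and 3.25, near the low end of the array signals. A fall of these genes could hardly show, so the test cannot exclude a wider fall. Whether a single mutant array carried a list shift could not be decided, as no shift was found (medians from -0.08 to -0.04 without 1 mutant array).

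Among the 40 named genes nearest to YAF9A, 20 on each side in the order of TAIR10.1, 6 changed, and 4 changed near YAF9B, against a 95th percentile of 9 in windows of the same size across the genome. Of 45 bacterial and phage control probe sets, 0 passed the threshold by limma, at an unadjusted p of 0.05 as well, with log2 changes from -0.16 to 0.15. Of 19 Arabidopsis control probe sets, 0 passed, and 4 had an unadjusted p under 0.05, all of them ubiquitin probe sets with log2 changes from -0.29 to -0.21.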
